A study of Apis mellifera and Octopus bimaculoides and Monodelphis domestica with 11 samples.

How the data were processed

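The series covers 11 samples. Of these, 10 are bisulfite methylomes of nervous tissue from several animal species, each sample standing alone under its own species and region, and 1 is an RNA sequencing library from the whole brain of a honeybee (Apis mellifera) queen. Values for the 10 methylomes were not used here, so methylation was not analysed here. One processed table was analysed, that of the RNA library. Per the labels' protocols, its RNA was extracted with Trizol and made into a strand-specific library after poly-A selection, which enriches for messenger RNA.

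The table lists 15314 targets, 1 row for each honeybee gene model, with the length, the effective length, the estimated count and the TPM of each. Per the file headers, the authors deposited estimated counts, meaning reads assigned to a target after reads that match several targets have been divided between them. Per the file headers, the deposited TPM (a relative transcript abundance with the same sum in every library) is normalised for length and depth. Recomputing it as the estimated count divided by the effective length and scaled to a common sum returned the deposited values with a largest difference of 0.0011%. The column names are those that the quantifier kallisto writes, but the program, its options, the use of the strand and the set of gene models are not given in the sources used here. The submitters' processing notes name CASAVA 1.8.2, fastp, Bowtie2 and BS-Seeker2 and a chicken genome build for all samples alike, and none of these says how the honeybee RNA was quantified. Counts are printed with at most 6 significant digits, so for the 3 targets above 100000 counts a fractional part cannot be seen.

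Properties of the table that bear on the measurements were tested on the values. The effective length differed between targets of the same length for 94.4% of the 2409 lengths held by several targets, and it exceeded the full length for 39 targets. The full length was a multiple of 3 for 66.7% of targets, with 2530 and 2563 targets at the other two remainders. If gene models that hold untranslated sequence fall evenly on the remainders, about 50.1% of the models hold coding sequence alone. For short targets the effective length is a small part of the full length (a median of 37.5% in the shortest length class), which raises their TPM per read.

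No target was given a gene name. The identifiers have the form of a prefix and a number, and 0 of the 15314 matched an identifier, accession or synonym among the 12398 genes of the reference table used (assembly Amel_HAv3.1). Names were not inferred in any other way, and no coordinates are given. The 17 gene lists fixed before the data were examined (DNA methylation enzymes and readers, synaptic, transmitter, neuropeptide, clock, glial, retinal, gland, fat body, muscle and other lists) therefore had 0 measured members that could be identified, and none has a result. The planned relation of expression to CpG content was not run because transcript sequence was not used here. The naming rule fixed beforehand took the 20 targets of highest TPM. Because they carry no gene names, the first 2 are given by identifier and the other 18 are summarised.

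The library is a single sample, so there is no estimate of the variation between animals, no difference between groups was tested and no p-value is given. A target was called detected at 1 TPM or more. Shares of counts and of targets carry 95% Wilson intervals. For shares of counts these cover counting error only, since reads without molecular identifiers are not independent molecules. For shares of targets they treat gene models as independent draws and hold no counting error of the reads. A target with a count of 0 was given an upper limit of 3 counts. At 1 TPM a target has 10.6 estimated counts per 1000 bases of effective length. Targets were divided into 5 classes of about equal size by length. A count was called fractional when it lay more than 0.001 from a whole number. Rank correlations between targets with adjacent identifier numbers are Spearman's rho across targets, which are not independent replicates, and are set beside the range of 1000 random orders. Where pairs were restricted to certain targets, the random orders paired all the targets kept. These are more pairs than were observed, so the range is somewhat too narrow there. On simulated data for the correlation of adjacent numbers, over 15314 targets, a planted rho of 0.29 came out as 0.26, while random order gave a value that differed from 0 by less than the range of random orders. For detection, 95.5% of 200 targets raised 4 times to above 1 TPM were recovered. These 200 were drawn from targets of longer effective length only, so the value does not cover short targets. Alternatives were other detection thresholds for the number of detected targets (0.1 TPM, 5 TPM, a count of 10), estimated counts in place of TPM for the share in the highest 20, and, added after the data were seen, the same thresholds for the detected share by length, TPM on the full length, TPM without the target of highest count and TPM of targets of at least 300 bases. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.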

Results

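The study profiled cytosine methylation in nervous tissue, mostly brain, of vertebrates and invertebrates. It also sequenced poly-A RNA from the whole brain of a honeybee queen, the reproductive female of the colony. The RNA library is described here. It held 13777163 estimated counts over 15314 gene models. With 1 library and no second group of the same assay, the values describe this sample and have no replicate error.

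Most gene models of the honeybee were represented in the queen brain RNA. At least 1 TPM was reached by 11404 of the 15314 targets (74.5%), and their median was 16.4 TPM, with quartiles at 6.28 and 42.7 TPM. A further 934 targets had counts but stayed under 1 TPM, and 2976 targets (19.4%) had a count of 0. The upper tail was narrow. At 10 TPM or more there were 7319 targets, at 100 TPM or more there were 1273, and 102 targets (0.67%) reached 1000 TPM. Those 102 targets together held 46.6% of the library's TPM and 38.8% of its counts.

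A single gene model took 25.2% of the estimated counts. The target GB49544, a model of 5429 bases, had 3476340 estimated counts, the highest number (95% Wilson interval of its share 25.2 to 25.3%, counting error only). The target next below it by count held 1.17% (1.16 to 1.17%), so that the first exceeded it 21.6-fold. Without GB49544, 10300823 counts remained for all other targets. Measured by TPM, which divides by effective length, GB49544 was second with 60538 TPM, or 6.05% of the total. The highest TPM belonged to GB43330, a model of 222 bases with 71454 TPM, or 7.15% of the total. That value rested on 62143 counts, 0.45% of the library (0.448 to 0.455%), which put GB43330 at rank 12 by count. Its first rank by TPM also rests on the effective length, which was 82.2 bases for GB43330 and 5429 bases for GB49544. Per base of full length, GB49544 had more counts than GB43330. The deposited table does not pair either identifier with a gene name.

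The 20 targets of highest TPM held 32.3% of the library's TPM. Of this, 13.2% belonged to GB43330 and GB49544 and 19.1% to the other 18, which lay between 4238 and 32810 TPM. Those 18 were models of 108 to 1452 bases with 3196 to 145610 estimated counts each. The 20 targets of highest count held 34.7% of the counts, of which GB49544 accounted for 25.2% and the other 19 for 9.45%. Only 7 targets were in both sets of 20. The set ranked by TPM had a median length of 356 bases and contained 8 models under 300 bases. The set ranked by count had a median length of 2358 bases and contained 1 such model. The median over all targets was 1185 bases, and 19.7% of targets were under 300 bases.

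**Figure D1:**
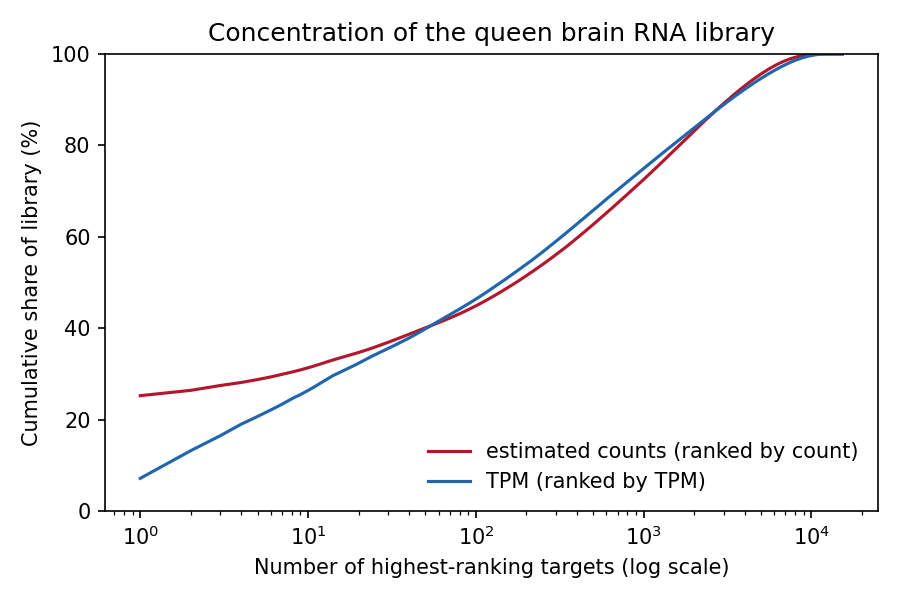
Cumulative share of the library (percent, vertical axis) held by the highest-ranking targets (number of targets, log scale), for estimated counts ranked by count (red) and TPM ranked by TPM (blue), in the single queen brain library. The first target by count (GB49544) held 25.2% of counts, and the first by TPM (GB43330) held 7.15% of TPM. The 1000 highest targets of each ranking held 72.5% of counts and 74.9% of TPM.

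Longer gene models were detected more often than short ones. In the shortest of 5 length classes of targets (78 to 305 bases), 43.6% reached 1 TPM (95% Wilson interval 41.9 to 45.4%), and 55.1% had a count of 0. With detection set at 10 estimated counts instead, the share in this class was 21.7%. In the following classes the detected share was 63.7%, 79.6% and 90.2%. In the longest length class (2748 to 70896 bases) it was 95.2% (94.4 to 95.9%), with 0.88% of targets at a count of 0. The intervals of the 5 classes, which treat gene models as independent, did not overlap. Over all targets, the median level rose with length, from 0 TPM in the shortest length class through 4.63, 11.2 and 13.7 TPM to 13.9 TPM in the longest. Among targets that were detected, the median level showed no steady trend with length. It went from 14.2 TPM in the shortest length class through 19.2, 18.7 and 16.3 TPM to 14.95 TPM in the longest. Detection keeps a different share of each class, so these medians do not describe all its models.

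**Figure D2:**
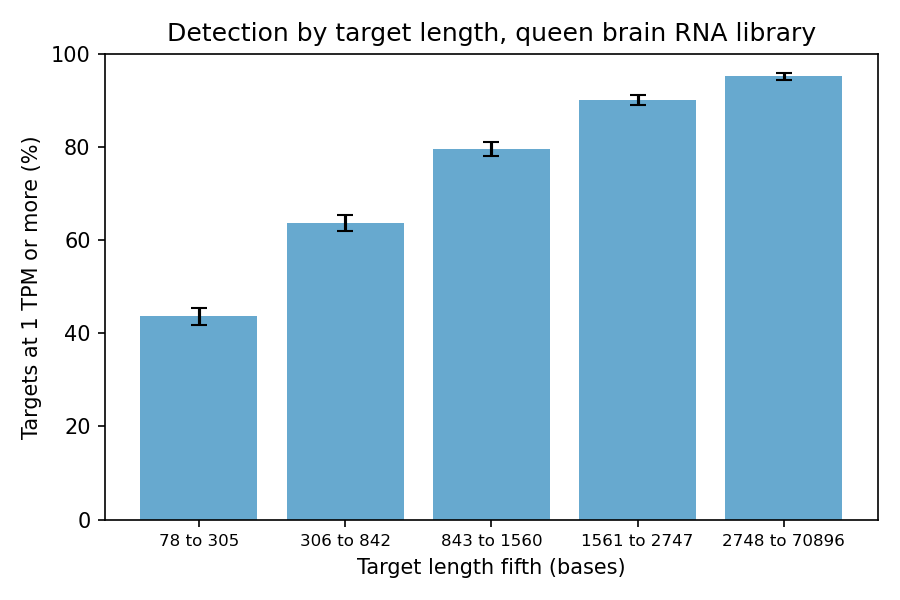
Share of targets at 1 TPM or more (percent, vertical axis) in 5 classes of target length (bases, horizontal axis), in the single queen brain library, with 95% Wilson intervals as error bars. The share was 43.6% in the shortest class and 95.2% in the longest.

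The depth limits what a low value means for a short model. At 1 TPM a target of median effective length in the shortest length class has 0.68 estimated counts, against 39.2 in the longest length class, so a single read lifts many short targets over the threshold. Of the 11404 detected targets, 295 rested on fewer than 3 counts. Of the 2976 targets with a count of 0, 2109 (70.9%) were so short that the limit of 3 counts corresponds to more than 1 TPM. For these, a level of 1 TPM cannot be excluded at this depth.

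Part of the signal could not be assigned to 1 gene model. Counts were fractional for 3174 targets, 25.7% of those with any count, and these targets held 25.4% of all counts. That share takes in the full count of each such target, so the share of reads that were divided is not known and may be smaller. The 3 targets above 100000 counts, GB49544 among them, were put with the whole counts because their decimals are not printed. They held 27.5% of all counts, so the share in fractional targets would be 52.8% if all 3 were fractional, and it was 35.0% of the counts outside them. Such counts arise when reads are divided between targets, and the split between the sharing models is uncertain. The median was 15.7 TPM for targets with fractional counts and 13.7 TPM for those with whole counts above 0. There were 5 sets of targets with identical length, fractional count and TPM.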

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

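The number of detected targets (11404) ranged from 9124 at 5 TPM to 12263 at 0.1 TPM over the 5 settings tried. All 5 were within 1.5 times of it, a bound that 15314 targets could not pass upwards. The share of TPM in the highest 20 targets (32.3%) was 34.7% with estimated counts. Among the settings added after the data were seen, it was 28.5% with only targets of at least 300 bases, 29.0% with TPM on the full length and 28.4% without GB49544, the target of highest count. Detection by length was recomputed only at settings added after the data were seen. In the shortest length class (43.6%) it was 32.0% at 5 TPM, 21.7% at a count of 10 and 40.4% on the full length. In the longest length class (95.2%) it was 98.6% at 0.1 TPM, 79.4% at 5 TPM and 97.8% at a count of 10. The longest length class was above the shortest at each of these settings. Settings that need gene names (gene list levels, methylation machinery, the top share without mitochondrial and ribosomal genes) or sequence (CpG content) were not run. Leaving out a replicate was not possible with 1 library.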

Other observations

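The patterns below were noticed in the data, and the test on shared reads and the restriction of fractional neighbours to counted targets were chosen after the results were seen. Gene models whose length is not a multiple of 3, which must hold untranslated sequence or an incomplete reading frame, were detected more often than the others. At least 1 TPM was reached by 89.9% of these 5093 targets (95% Wilson interval 89.0 to 90.7%) and by 66.8% of the 10221 targets with a length that is a multiple of 3 (65.9 to 67.7%). Part of this gap goes with length. Multiples of 3 made up 97.4% of targets in the shortest length class and 42.6% in the longest. Within each length class the difference had the same direction. The shares were 76.1% (72.6 to 79.4%) against 60.6% (58.6 to 62.5%) in the second length class. They were 86.4% against 75.9% in the third, 92.2% against 88.1% in the fourth and 96.4% (95.4 to 97.2%) against 93.6% (92.2 to 94.8%) in the longest. In the shortest length class, where 81 targets were not multiples of 3, the intervals overlapped, with 53.1% (42.3 to 63.6%) against 43.4% (41.6 to 45.2%). No explanation of the difference within length classes was tested.

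Targets with adjacent identifier numbers had similar levels. Spearman's rho of TPM across the 15313 adjacent pairs was 0.28, where 1000 random orders gave -0.029 to 0.024. It was 0.18 for targets 2 places apart, 0.10 at 5 places, 0.062 at 10 places and 0.0026 at 100 places, the last inside the range of random orders. Among pairs with both targets at 1 TPM or more, leaving out fractional counts did not lower the correlation. Visibly divided counts were therefore not its only source among those pairs. A whole count does not show that a target shares no reads, so reads shared between adjacent targets are not excluded. Over the 9783 pairs with whole counts, zeros included, rho was 0.37. Leaving out fractional counts raises the share of targets at 0, so this value cannot decide. Among pairs with both targets at 1 TPM or more it was 0.11 over all 9350 pairs and 0.13 over the 5306 with whole counts, above the highest random order (0.034). Similar length was not the whole source. The correlation was 0.21 for ranks taken within length decile and multiple-of-3 class, above the highest random order (0.024). Runs of undetected models alone were not the whole source. The 0.11 over pairs with both targets at 1 TPM or more was above the highest random order (0.032) and below the 0.28 for all pairs. Length and detection were each restricted alone, so both together are not excluded as the source. A hypothesis that stays open is that the numbers follow position in the genome and that neighbouring genes have similar levels in this brain. Pieces of 1 gene annotated under adjacent numbers may also contribute. Neither was tested, because positions of the targets were not used here, and no biological explanation was tested.

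Of the 20 targets of highest TPM, 8 were models under 300 bases. These 8 had 3196 to 62143 estimated counts and ranked 12 to 599 by count, all 8 within the top 5% of targets. These ranks cannot decide on few reads scaled up by a short length, because for 6 of the 8 a TPM high enough to enter the 20 already required a count in that top 5%. The lowest of the 8 counts was 3196, against a median of 92 over all targets. The second explanation was an effective length shorter than target length, which was a median of 37.8% of the full length for these 8. With TPM recomputed on the full length, 16 of the 20 targets stayed among the highest 20 and 5 of the new 20 were under 300 bases. That number lies between the bounds set beforehand (at most 4 if the effective length were the cause, at least 7 if not), so the effective length may place some of them, and its share stays open.

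The target after a fractional count was itself fractional more often than the target after a whole count was. Among pairs of adjacent targets that both had counts, which leaves out the targets at 0, the next target was fractional in 30.7% of the 2659 pairs after a fractional count (95% Wilson interval 29.0 to 32.5%) and in 23.3% of the 7987 pairs after a whole count (22.4 to 24.3%). With targets at 0 included, the shares were 25.7% and 19.4%.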
